A study of Homo sapiens with 8 samples.

How the data were processed

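RNA from HepG2 cells was sequenced as 4 mock and 4 EDN1 overexpression libraries, prepared with a Lexogen QuantSeq kit per the labels' protocols, a kit that reads tags near the end of polyadenylated transcripts. The deposited table holds raw read counts per gene, 1 column for each library, and a gene length. Bowtie2, edgeR and the human genome build hg19 are named per the submitters' processing notes. The versions, the counting tool, its filters and its use of strand are not given in the sources used here, so overlapping and antisense genes such as ACTA2 and its antisense partner cannot be told apart.

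Groups and replicate numbers were taken from the sample titles. The table had 25737 rows, and 288 symbols stood on more than 1 row. Rows of 1 symbol were summed, except MARCH1 and MARCH2, which each stand for different genes, leaving 24462 genes. Mitochondrially encoded genes had 0 rows in the table used here. Total counts ranged from 8409173 to 14932385 per library.

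Genes were filtered with edgeR's filterByExpr (minimum count 10) by group, leaving 12577, and scaled by TMM. The main test was edgeR's quasi-likelihood test (edgeR 4.0.16, R 4.3.3) on counts with the group as the only term, Benjamini-Hochberg adjustment and a threshold of 0.05. Standard errors were the fold change divided by the square root of the F statistic, and intervals are 95% intervals. CPM values of single genes use TMM-scaled library sizes. Summed markers and the floor of 3 counts use the library totals. On simulated counts of 12453 tested genes with 200 changed genes, edgeR made 9 false calls and recovered 50 of 50 genes changed 8-fold. The simulation held no structure between libraries other than the group. Every pair of libraries differed by more than sampling noise, with chi-square per degree of freedom from 6.49 to 92.7.

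Gene lists, 38 in all, were written before the data were examined, and 35 had at least 4 measured members. They were tested by camera (limma 3.58.1) on voom values with a preset correlation of 0.01, with an estimated correlation and fry as alternatives. A list score is the mean over members of log2 CPM (prior count 2) centred on each gene's mean over the 8 libraries, compared by an exact two-sided permutation test. Beside the lists in the report, camera did not call fatty acid oxidation (adjusted p = 0.614), lipoprotein assembly (0.709), complement and coagulation (0.147), hepatocyte transcription factors (0.27), drug and bile acid metabolism (0.797), interferon response (0.891), extracellular matrix (0.962), YAP/TEAD targets (0.308), Wnt targets (0.72), metallothioneins (0.0831), heat shock proteins (0.282), angiogenic factors (0.804), fetal liver markers (0.18), oxidative phosphorylation (0.282), histones (0.891) or apoptosis and autophagy (0.153). Camera also did not call biliary (0.179), fibroblast (0.875) or blood and immune markers (0.962). Some of these were called under alternatives, though over all libraries the adjusted p with an estimated correlation was at least 0.536 for each of them. Metallothioneins were called lower without the low count filter (camera adjusted p = 0.0184), without mock 2 (0.0134), without EDN1 1 (0.0241) and with 2 surrogate variables (6.28e-04). Complement and coagulation was called lower without mock 1 (0.00154), EDN1 2 (0.0143) or EDN1 4 (0.0198), fetal liver markers lower without mock 1 (0.0381) and YAP/TEAD targets lower without EDN1 4 (0.0441). Heat shock proteins were called higher without mock 2 (0.0245) or EDN1 2 (0.0178). In the second set alone, with its lone mock library, camera called lower metallothioneins (3.72e-04), complement and coagulation (0.0179), fetal liver markers (0.00746), YAP/TEAD targets (0.00754), hepatocyte transcription factors (0.0171) and histones (0.00746).

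Named genes followed a rule fixed before the data were examined: the endothelin system, up to 12 genes per direction past the threshold with at least 10 CPM and groups that do not overlap (only EDN1 met this), up to 4 members with the smallest adjusted p of each described list, with ties broken by the unadjusted p, and the 5 most counted genes. Since list members were picked by p in these libraries, their fold changes are the larger ones of each list.

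Alternatives planned before the data were examined were other scalings, other filters, DESeq2 1.42.0, limma voom, the replicate number as a block, stricter thresholds, other set tests and leaving out each library. Alternatives chosen after seeing the data were the library set as a term or each set alone, 1 or 2 surrogate variables (sva 3.50.0), rows kept as deposited, DESeq2 with the library set, each library left out of the comparison between the sets, a permutation of list scores and removal of each library's lowess trend (span 0.3) on transcript GC content. The GC content came from transcripts of another annotation, matched by symbol for 11870 of the tested genes, and no coordinates were used.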

Results

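Gene expression was measured by RNA sequencing in HepG2 cells, a human line derived from a liver tumour, in a group labelled mock and a group with EDN1 overexpression. EDN1 encodes the precursor of endothelin-1, a secreted vasoconstrictor peptide. Each group held 4 libraries. Total counts per library ranged from 8409173 to 14932385 in mock and from 8571252 to 11686180 in EDN1 overexpression. After the filter on low counts, 12577 genes were tested. The labels do not say whether the 4 libraries of a group came from separate cultures, so p-values measure only the spread between these libraries.

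The comparison asked what EDN1 overexpression changed in the HepG2 transcriptome. EDN1 itself rose from 1.45 ± 0.561 CPM (the usual count scaled by library size) in mock to 363 ± 149 CPM in EDN1 overexpression (mean ± SD, n = 4 each). This was a log2 fold change of 7.92 (SE 0.41, 95% interval 7.02 to 8.82), or 242-fold. Its adjusted p was 1.68e-05 in edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment. The EDN1 counts were 29, 9, 9 and 20 in mock 1 to 4 and 2803, 2284, 4764 and 4752 in EDN1 overexpression 1 to 4, so every library matched its label. The counts do not separate transcripts of an introduced copy from those of the endogenous gene.

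**Figure D1:**
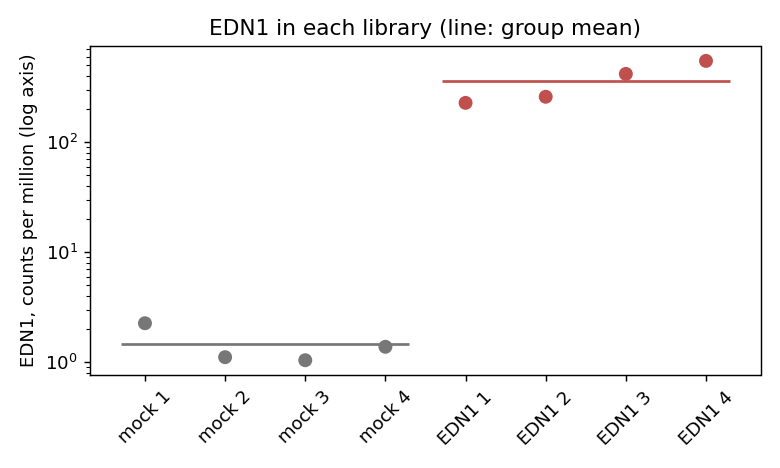
EDN1 expression in CPM on a log axis for each of the 8 libraries (points), with the group mean as a line. The mock libraries average 1.45 CPM and the EDN1 overexpression libraries 363 CPM, with no overlap.

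Other members of the endothelin system did not pass the test or were at the limit of detection. ECE1, which encodes an endothelin-converting enzyme, had a log2 fold change of 0.43 (SE 0.25) from 142 CPM in mock, which was 0.65 without mock 4 and 0.25 without EDN1 3. ECE2, a related enzyme gene, had a log2 fold change of -0.34 (SE 0.27) from 9.53 CPM, which was -0.54 without EDN1 2 and -0.19 without mock 3. The receptor gene EDNRA had at most 2 counts in any library, and the receptor gene EDNRB had 0 counts in all 8. EDN3 and KEL also had 0 counts, EDN2 at most 1 and MME at most 2. A count of 0 allows up to 3 counts, which is 0.201 to 0.357 CPM depending on the library. These limits cover counting error only.

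The 8 libraries also differed in a way that did not follow the groups. Mock 4, EDN1 3 and EDN1 4 (called here the second library set) stood apart from the other 5 libraries (the first library set), and no label gives a batch. In a fit with the group as a term, 1876 genes differed between the sets by edgeR's quasi-likelihood test, 664 higher and 1212 lower in the second set. The count was 296 without mock 4, 949 without EDN1 2 and 1053 without EDN1 1. It rose to 2602 without mock 2 and was 1253 to 1644 without each of the other libraries. The sets were formed from these same counts, so the p-values of differences between them are not independent evidence. CDK4, a cell cycle kinase gene, averaged 295 CPM in the first set and 45.1 CPM in the second, a log2 difference of -2.75 (SE 0.21) with an adjusted p of 1.14e-04 in edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment. MMACHC, a cobalamin metabolism gene, averaged 309 CPM in the first set and 1537 CPM in the second. CDK4 and MMACHC were chosen after their values were seen. Values within each set are therefore given beside those over all libraries. The first set holds 3 mock and 2 EDN1 overexpression libraries and the second 1 mock and 2 EDN1 overexpression libraries. Values within the second set assume that its lone mock library varies like the EDN1 libraries. EDN1 had a log2 fold change of 7.28 (SE 0.29) within the first set and 8.43 (SE 0.71) within the second. ECE1 had log2 fold changes of 0.23 (SE 0.17) and 0.24 (SE 0.42) within the first and second sets, against 0.43 over all libraries, and ECE2 -0.19 (SE 0.27) and -0.18 (SE 0.57), against -0.34.

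**Figure D2:**
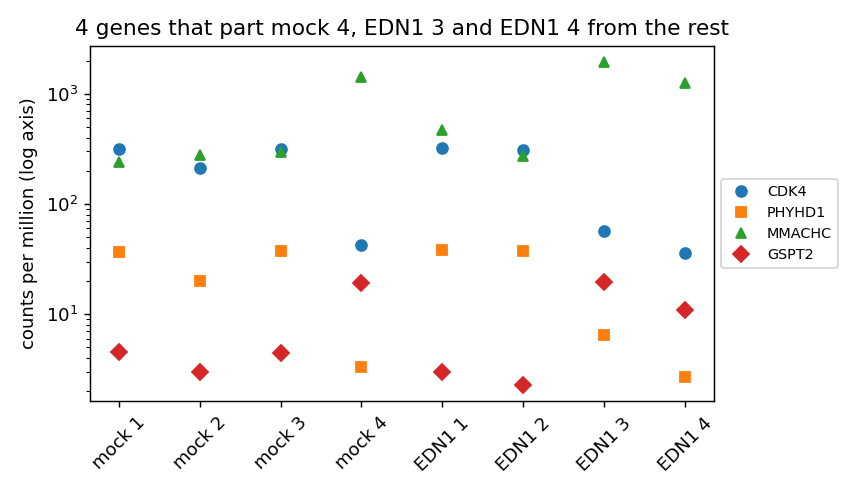
Expression in CPM on a log axis of CDK4, PHYHD1, MMACHC and GSPT2 in each of the 8 libraries, 1 point per library. Mock 4, EDN1 3 and EDN1 4 lie apart from the other 5 libraries, with CDK4 at 42.4, 57.2 and 35.8 CPM against a mean of 295 CPM.

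Of the 12577 genes, 1 was higher (EDN1) and 0 were lower in EDN1 overexpression by edgeR's quasi-likelihood test. The next smallest adjusted p was 0.372, for TMSB4X, by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment. At an unadjusted p under 0.05 there were 359 genes, where 629 are given by chance if p-values are evenly spread. Over the other splits of the 8 libraries into 4 and 4 the number ran from 25 to 3370, so 629 is a poor guide here. The count of 359 depended on single libraries. It was 184 without EDN1 3, 220 without mock 3, 229 without EDN1 1, 576 without mock 4, 641 without EDN1 2 and 738 without EDN1 4. It was 550 with the replicate number as a block, 627 with 1 surrogate variable and 1139 with 2, so it does not settle whether more genes than by chance differed. Surrogate variables were estimated from these same libraries with the group difference kept, so p-values with them may be too small, those of single genes included. The 4 libraries of one group did not overlap the 4 of the other in 257 genes, 2.04% of those tested, where chance gives 2.86%. limma voom also called 1 gene, and DESeq2 called 2 higher (EDN1 and TMSB4X) and 1 lower (LGI1). TMSB4X, an actin-binding peptide gene, averaged 1.29 ± 0.469 CPM in mock and 5.27 ± 1.01 CPM in EDN1 overexpression (SD, n = 4). LGI1 averaged 3.77 ± 1.28 CPM in mock and 0.791 ± 0.493 CPM in EDN1 overexpression (SD, n = 4). TMSB4X and LGI1 are outside the rule for named genes and were named because DESeq2 called them. DESeq2 with the library set as a term also called both (adjusted p = 0.00103 and 0.044), and edgeR's quasi-likelihood test with 2 surrogate variables called TMSB4X (adjusted p = 0.0345, Benjamini-Hochberg). By set, first and second, the log2 fold changes were 2.25 and 1.43 for TMSB4X and -2.12 and -2.61 for LGI1. With the library set as a term, edgeR called 1 gene, and within the first set alone it also called 1. It called 1 in the second set, where the lone mock library limits the test.

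The precision of the comparison limits what these counts exclude. The 95% interval of the fold change lay within 2-fold in either direction for 79.4% of the genes and within 4-fold for 98.9%. In simulated counts with the spread of these libraries, edgeR recovered 0 of 50 genes changed 1.5-fold. It recovered 18 of 50 changed 2-fold and 44 of 50 changed 4-fold. The simulated counts held many changed genes and no structure other than the group. Benjamini-Hochberg adjustment is less strict when many genes change, so these shares may overstate what could be recovered here. TMSB4X, for example, had a fold change of 3.93 and an adjusted p of 0.372 by edgeR's quasi-likelihood test.

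Genes were next compared by the 35 lists with enough measured members. No list member other than EDN1 passed the test over all genes. Camera with a preset correlation of 0.01 called 5 lists higher and 9 lower, and none of these calls held with an estimated correlation, where the smallest adjusted p was 0.36 by camera with Benjamini-Hochberg adjustment. fry also called 0 lists. Leaving out EDN1 3 lowered the number of lists called from 14 to 7, leaving out EDN1 1 lowered it to 8 and leaving out mock 4 lowered it to 9. These are net counts, in which new calls can hide lost ones. Leaving out mock 2 ended the fatty acid, secreted protein, glycolysis, gluconeogenesis, G2/M and p53 calls, while other lists were newly called. Mock 2 had the lowest G2/M score of the 8 libraries (-0.70) and the highest acute phase (0.59), glycolysis (0.33) and ribosomal protein scores (0.36). All list values below are therefore descriptions of these 8 libraries. In 12 of the 14 lists the scores of EDN1 1 and EDN1 3 both lay outside the range of the mock libraries, and in 6 of these the scores of EDN1 2 and EDN1 4 both lay within it. EDN1 1 is in the first library set and EDN1 3 in the second, so values within the sets do not separate this from the group. These ranges were looked at after the data were seen, and the 14 lists were called on the same libraries. Of the lists not called, only complement and coagulation, YAP/TEAD targets, Wnt targets, and apoptosis and autophagy had EDN1 1 and EDN1 3 both outside. Glycolysis is counted in both tallies, though EDN1 1 lay barely below the mock range (-0.1972 against -0.1964).

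Cholesterol synthesis genes had positive fold changes in 21 of 23 measured members, with a median log2 fold change of 0.56. Adjusted over the list alone, 7 members passed, all higher, while 0 passed over all genes tested. With 2 surrogate variables, chosen after seeing the data, EBP passed over all genes in edgeR's quasi-likelihood test (adjusted p = 0.0485, Benjamini-Hochberg). EBP, a sterol isomerase gene, averaged 29.5 ± 7.70 CPM in mock and 59.4 ± 15.6 CPM in EDN1 overexpression (SD, n = 4), with a log2 fold change of 1.01 (SE 0.24). HMGCS1, which encodes an early enzyme of the pathway, averaged 64.9 ± 13.4 and 142.6 ± 70.8 CPM, with a log2 fold change of 1.13 (SE 0.32). The log2 fold changes were 0.85 (SE 0.20) for DHCR7 and 0.80 (SE 0.24) for FDFT1. Camera called the list higher with an adjusted p of 1.08e-12 at the preset correlation, against an adjusted p = 0.36 with an estimated correlation. The list score, the mean centred log2 CPM of its members, was 0.47 higher in EDN1 overexpression (exact permutation test, two-sided p = 0.0571, where 0.0286 is the smallest possible). It was 0.55 in EDN1 1 and 0.51 in EDN1 3, but -0.02 in EDN1 2 and -0.11 in EDN1 4, and lay between -0.33 and -0.11 in mock. The difference was 0.50 within the first library set and 0.44 within the second. The log2 fold changes within the first and second sets were 1.02 and 0.90 for EBP, 0.91 and 1.05 for HMGCS1, 0.88 and 0.78 for DHCR7 and 0.82 and 0.73 for FDFT1.

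Fatty acid and triglyceride synthesis genes had positive fold changes in 13 of 21 members, and 0 passed either over all genes or adjusted over the list alone. The desaturase gene FADS1 had a log2 fold change of 0.43 (SE 0.13), and SCD, another desaturase gene, one of 0.54 (SE 0.22), which was 0.34 without EDN1 3. The list score was higher in each EDN1 overexpression library than in every mock library, by 0.17 on average (exact permutation test, two-sided p = 0.0286, adjusted over the lists 0.81). The difference was 0.14 within the first library set and 0.17 within the second, with log2 fold changes of 0.41 and 0.42 for FADS1 and 0.39 and 0.45 for SCD. Camera called the list higher with an adjusted p of 0.0283, against an adjusted p = 0.36 with an estimated correlation. The correlation estimated for this list was -0.009, below the preset 0.01, so correlated members do not account for the loss of the call. Leaving out mock 2, mock 4, EDN1 3 or EDN1 4 ended that call, with adjusted p up to 0.109 by camera, and so did the library set as a term (0.0694) and the first set alone (0.234).

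**Figure D3:**
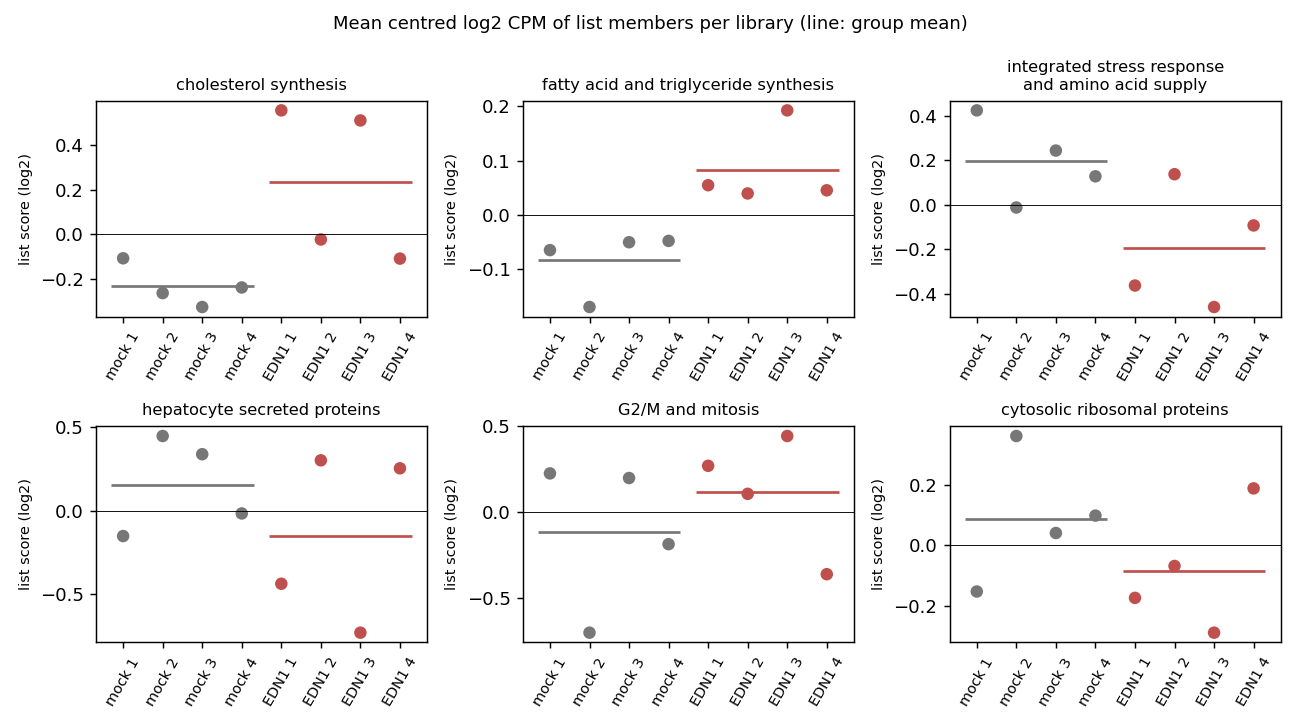
List scores, the mean centred log2 CPM of the measured members of 6 lists, for each of the 8 libraries (points) with the group mean as a line. The cholesterol synthesis score is 0.55 in EDN1 1 and 0.51 in EDN1 3 but -0.02 in EDN1 2 and -0.11 in EDN1 4.

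Genes of the integrated stress response and amino acid supply had negative fold changes in 24 of 26 members, with a median log2 fold change of -0.39, and 0 passed either over all genes or adjusted over the list alone. PHGDH, which encodes the first enzyme of serine synthesis, averaged 107 ± 24.4 CPM in mock and 67.3 ± 15.7 CPM in EDN1 overexpression (SD, n = 4), with a log2 fold change of -0.67 (SE 0.21). The stress-induced transcription factor gene ATF3 had a log2 fold change of -0.82 (SE 0.35), which was -0.51 without mock 1, and STC2 one of -0.59 (SE 0.21). Camera called the list lower with an adjusted p of 2.49e-11, against an adjusted p = 0.36 with an estimated correlation. The score was -0.36 in EDN1 1 and -0.46 in EDN1 3, but 0.14 in EDN1 2 and -0.09 in EDN1 4, and lay between -0.01 and 0.42 in mock. The score difference was -0.33 within the first library set and -0.40 within the second. By set, the log2 fold changes were -0.66 and -0.59 for PHGDH, -0.76 and -0.71 for ATF3 and -0.51 and -0.66 for STC2. Unfolded protein response and chaperone genes had positive fold changes in 18 of 24 members and were not called by camera (adjusted p = 0.136, and adjusted p = 0.67 with an estimated correlation). Camera called that list higher without mock 2 (adjusted p = 0.0288) and with 2 surrogate variables (0.0354), an alternative chosen after seeing the data, while its adjusted p was 0.963 without mock 1. Its score differed by 0.09 within the first set and 0.04 within the second. CRELD2 in that list had a log2 fold change of 0.73 (SE 0.33), with 0.84 and 0.50 within the sets.

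Immediate early and MAPK feedback genes had negative fold changes in 20 of 23 members, and 0 passed either over all genes or adjusted over the list alone. MYC had a log2 fold change of -0.51 (SE 0.25). Camera called the list lower with an adjusted p of 1.01e-05, against an adjusted p = 0.52 with an estimated correlation. NF-kB and inflammatory cytokine genes had negative fold changes in 10 of 13 members (camera adjusted p = 0.0407, and adjusted p = 0.57 with an estimated correlation). NFKBIA in that list had a log2 fold change of 0.37 (SE 0.21), which was 0.24 without EDN1 3, and NFKB2 one of -0.45 (SE 0.22). NRF2 and oxidative stress genes had negative fold changes in 16 of 24 members (camera adjusted p = 0.00505, and adjusted p = 0.52 with an estimated correlation), with AKR1C2 at a log2 fold change of -0.49 (SE 0.20). In both of these lists 0 members passed either over all genes or adjusted over the list alone. Leaving out mock 1, mock 4, EDN1 1 or EDN1 3 ended the call of the NF-kB list (camera adjusted p up to 0.391), the first set alone ended it too (0.133), and leaving out mock 4 or EDN1 1 ended that of the NRF2 list (up to 0.0773). The immediate early score was -0.42 in EDN1 1 and -0.39 in EDN1 3, but 0.18 in EDN1 2 and 0.08 in EDN1 4, which lay within the mock range of -0.09 to 0.36. The NF-kB score was -0.24, 0.12, -0.47 and 0.25 in EDN1 1 to 4, of which EDN1 3 alone lay outside the mock range of -0.36 to 0.44. The NRF2 score was -0.20, -0.05, -0.20 and 0.14 in EDN1 1 to 4, with EDN1 4 within the mock range of 0.00 to 0.15. Within the first and second library sets the score differences were -0.26 and -0.30 for the immediate early list, -0.11 and -0.33 for the NF-kB list and -0.18 and -0.15 for the NRF2 list. The log2 fold changes within the sets were -0.51 and -0.56 for MYC, 0.27 and 0.21 for NFKBIA, -0.51 and -0.19 for NFKB2 and -0.61 and -0.41 for AKR1C2.

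Acute phase protein genes had negative fold changes in 11 of 12 members, with the iron regulator gene HAMP at a log2 fold change of -0.60 (SE 0.22) and the fibrinogen gene FGG at -0.47 (SE 0.21). Camera called this list lower with an adjusted p of 5.45e-04, against an adjusted p = 0.52 with an estimated correlation. Hepatocyte secreted protein genes had negative fold changes in 12 of 14 members (camera adjusted p = 0.0185, and adjusted p = 0.57 with an estimated correlation), with RBP4 at a log2 fold change of -0.61 (SE 0.38), which was -0.91 without EDN1 2 and -0.37 without EDN1 3. Glycolysis and hypoxia genes had negative fold changes in 16 of 28 members (camera adjusted p = 0.0266, and adjusted p = 0.54 with an estimated correlation), with VEGFA at -0.62 (SE 0.28) on the log2 scale. Gluconeogenesis and FOXO target genes had negative fold changes in 10 of 13 members (camera adjusted p = 0.0266, and adjusted p = 0.54 with an estimated correlation), with TRIB1 at -0.53 (SE 0.27), which was -0.32 without mock 1. In each of these lists 0 members passed either over all genes or adjusted over the list alone. The secreted protein call ended without mock 2, mock 3, EDN1 1 or EDN1 3 (camera adjusted p up to 0.305). The gluconeogenesis call ended without mock 2, mock 3, mock 4, EDN1 1 or EDN1 3 (up to 0.308) and in the second set alone (0.0734). The glycolysis call ended without mock 2, mock 3, mock 4, EDN1 1 or EDN1 4 (up to 0.189), with the library set as a term (0.0758) and in the first set alone (0.234). Within the first and second library sets the score differences were -0.28 and -0.41 for acute phase genes, -0.28 and -0.22 for secreted proteins, -0.12 and -0.21 for glycolysis and -0.29 and -0.17 for gluconeogenesis. EDN1 1 and EDN1 3 lay below the mock range in all 4 lists, though for glycolysis EDN1 1 did so barely (-0.1972 against -0.1964). EDN1 2 and EDN1 4 lay within the range or, for gluconeogenesis in EDN1 4, above it. In EDN1 1 to 4 the acute phase score was -0.36, 0.22, -0.68 and 0.08 (mock -0.14 to 0.59), the secreted protein score -0.44, 0.30, -0.73 and 0.25 (mock -0.15 to 0.44), the glycolysis score -0.20, 0.15, -0.27 and -0.03 (mock -0.20 to 0.33) and the gluconeogenesis score -0.48, 0.17, -0.45 and 0.27 (mock -0.02 to 0.23). The log2 fold changes within the sets were -0.48 and -0.53 for HAMP, -0.50 and -0.48 for FGG, -0.41 and -0.20 for RBP4, -0.56 and -0.68 for VEGFA and -0.36 and -0.40 for TRIB1.

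Cell cycle genes had mostly positive fold changes, in 22 of 26 members of the G1/S list and 23 of 26 members of the G2/M list. The cyclin gene CCND2 had a log2 fold change of 0.41 (SE 0.17), and UBE2C, a mitotic ubiquitin-conjugating enzyme gene, one of 0.66 (SE 0.27). Camera called both lists higher, with adjusted p of 0.00203 for G1/S and 0.0013 for G2/M, against an adjusted p = 0.59 and an adjusted p = 0.67 with an estimated correlation. The G1/S call ended without EDN1 1 or EDN1 3 (camera adjusted p up to 0.203) and in the second set alone (0.158), and the G2/M call without mock 2 or EDN1 3 (up to 0.624). The p53 target list had positive fold changes in 16 of 22 members (camera adjusted p = 0.0407, and adjusted p = 0.54 with an estimated correlation), with PHLDA3 at a log2 fold change of 0.36 (SE 0.16) and the apoptosis gene PMAIP1 at -0.43 (SE 0.17). That call ended without mock 2, mock 3, EDN1 1, EDN1 3 or EDN1 4 (up to 0.299), with the library set as a term (0.0882) and in the first (0.17) and second set alone (0.545). Cytosolic ribosomal protein genes had negative fold changes in 67 of 77 members, with a median log2 fold change of -0.18 (camera adjusted p = 1.01e-08, and adjusted p = 0.57 with an estimated correlation). RPL39 had a log2 fold change of -0.41 (SE 0.22), which was -0.22 without mock 2, and ribosomal protein genes have many near-identical pseudogene copies, so their counts are uncertain. In each of these lists 0 members passed either over all genes or adjusted over the list alone. Within the first and second library sets the score differences were 0.29 and 0.07 for G1/S, 0.28 and 0.23 for G2/M, 0.11 and 0.05 for p53 targets and -0.20 and -0.15 for ribosomal proteins. The p53 score was 0.02 in EDN1 1 and -0.02 in EDN1 2, within the mock range of -0.20 to 0.08, and 0.13 in EDN1 3 and in EDN1 4. Its 3 highest scores were those of the second library set, with mock 4 at 0.08. In EDN1 1 to 4 the G1/S score was 0.35, 0.10, 0.33 and -0.46 (mock -0.25 to 0.07), the G2/M score 0.27, 0.11, 0.44 and -0.36 (mock -0.70 to 0.23) and the ribosomal protein score -0.17, -0.07, -0.29 and 0.19 (mock -0.15 to 0.36). The log2 fold changes within the sets were 0.38 and 0.45 for CCND2, 0.67 and 0.56 for UBE2C, 0.32 and 0.48 for PHLDA3, -0.46 and -0.51 for PMAIP1 and -0.40 and -0.34 for RPL39.

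Epithelial-mesenchymal transition genes were not called (camera adjusted p = 0.742), with 9 of 16 members positive. The list mixes epithelial genes such as CDH1 with other genes of the transition, so a test in 1 direction does not decide whether a transition occurred. CDH1, the E-cadherin gene, averaged 63.1 ± 18.5 CPM in mock and 127.4 ± 43.6 CPM in EDN1 overexpression (SD, n = 4), with a log2 fold change of 1.01 (SE 0.27) that did not pass the test, and an adjusted p over the list alone of 0.0544 by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment. Within the first and second sets it was 0.81 and 0.83. CDH1 passed over all genes in DESeq2 with the library set as a term (adjusted p = 0.0287) and in edgeR's quasi-likelihood test with 2 surrogate variables (adjusted p = 0.0199, Benjamini-Hochberg), both chosen after seeing the data, and its adjusted p ranged up to 1.00 over its 26 alternatives. Summed markers of other cell types did not pass the test. Summed biliary markers were 1106 ± 60.2 CPM in mock and 1302 ± 193 CPM in EDN1 overexpression (SD, n = 4, exact permutation test, two-sided p = 0.143), of which KRT19 was the most abundant. KRT19 had a log2 fold change of 0.61 (SE 0.30), which was 0.38 without EDN1 3, and 0.65 and 0.45 within the sets. Fibroblast and stellate markers summed to 155 ± 76.5 and 157.5 ± 120.5 CPM (exact permutation p = 0.971), endothelial markers to 7.77 ± 1.41 and 8.15 ± 1.85 CPM (exact permutation p = 0.686) and blood and immune markers to 646 ± 155 and 551 ± 190.5 CPM (exact permutation p = 0.457). LYZ averaged 571 CPM over all libraries and was most of the blood and immune sum, which is thus mainly the level of 1 gene. ACTA2, the largest part of the fibroblast sum, averaged 197 CPM in the first set and 34.1 CPM in the second. Its antisense partner ACTA2-AS1 averaged 197 and 33.1 CPM. Counts of these overlapping genes cannot be told apart, so this sum need not be a level of fibroblast markers. The fibroblast sum was 193 CPM in mock and 259 CPM in EDN1 overexpression within the first set, and 41.6 and 56.2 CPM within the second. The score of that list differed by 0.05 over all libraries but by 0.21 and 0.19 within the sets, so the pooled sums do not show that these markers were equal. Biliary sums were 1111 and 1380 CPM within the first set and 1094 and 1223 CPM within the second, and the biliary list was called by camera with 2 surrogate variables (adjusted p = 0.0303), against an adjusted p = 0.57 with an estimated correlation and no surrogate variable. Endothelial sums were 7.95 and 9.70 CPM and 7.23 and 6.59 CPM, and blood and immune sums 629 and 508 CPM and 697 and 594 CPM. Camera called the blood and immune list lower in the second set alone (adjusted p = 2.64e-04), which holds a lone mock library, against an adjusted p = 0.98 with an estimated correlation over all libraries.

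The 5 most counted genes had overlapping groups. FN1, the fibronectin gene, averaged 25559 ± 9980 CPM in mock and 26784 ± 13142 CPM in EDN1 overexpression (SD, n = 4), and RPS27A 12755 and 13150 CPM. GDF15 averaged 13634 and 9313 CPM, IER3 6714 and 4948 CPM and HSP90AB1 5321 and 5675 CPM. FN1 had a log2 fold change of 0.07 (SE 0.37) over all libraries but -0.25 and -0.08 within the first and second sets, and ran from -0.32 without EDN1 4 to 0.30 without mock 4. GDF15 had a log2 fold change of -0.55 (SE 0.37), which was -0.35 without EDN1 1 or EDN1 3 and -1.02 without EDN1 4. IER3 had one of -0.44 (SE 0.24), which was -0.69 without EDN1 2. The values within the sets were -0.13 and 0.06 for RPS27A, -0.81 and -0.45 for GDF15, -0.33 and -0.52 for IER3 and 0.00 and -0.01 for HSP90AB1.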

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

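The rule for a library far from the rest of its group was set before the data were examined. It marks a library whose gap to the nearest of the other 3 exceeds 0.829 of the group's range, and chance marks about 1 group in 20. Of 196 groups of 4 values, 11 were marked where 9.8 are given by chance. No explanation was tested for them.

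Among mock libraries, SLC7A11 was 482.5 CPM in mock 1, where the nearest was 394 CPM. In mock 4, SCD was 921 CPM with the nearest at 697 CPM, VTN was 9.19 CPM with the nearest at 20.7 CPM, and the biliary marker score was -0.24 with the nearest at -0.06. FGG was 55.8 CPM in mock 3 with the nearest at 69.5 CPM. In mock 2, SLBP was 24.7 CPM with the nearest at 28.2 CPM, and the fatty acid and triglyceride synthesis score was -0.17 with the nearest at -0.06.

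Among EDN1 overexpression libraries, CLDN1 was 114.9 CPM in EDN1 2 with the nearest at 78.4 CPM. In EDN1 4, DNAJC12 was 41.1 CPM with the nearest at 12.8 CPM, and PRSS56 was 4.73 CPM with the nearest at 11.2 CPM. The fatty acid and triglyceride synthesis score was 0.19 in EDN1 3 with the nearest at 0.05.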

How the results depend on the processing

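The alternatives with the library set, surrogate variables, rows as deposited, GC content and permuted list scores were chosen after seeing the data. EDN1 stayed past the threshold in all 26 alternatives, with log2 fold changes from 7.28 to 8.43, and from 7.65 to 8.23 when each library was left out. The number of genes called was 1 (1 higher, 0 lower) in each leave-one-out run. DESeq2 called 3 (2 higher, 1 lower), DESeq2 with the library set as a term 7 (5 higher, 2 lower) and edgeR with 2 surrogate variables 7 (6 higher, 1 lower), and the cause was not tested. Replicate numbers did not consistently pair the samples: same-number correlations of deviations were 0.48, 0.15, -0.15 and 0.53. Mock 4 also correlated at 0.52 with EDN1 3. A partial pairing is not excluded. With the replicate number as a block 1 gene and 14 lists were called.

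The 14 lists called by camera (5 higher, 9 lower) became 0 (0 higher, 0 lower) with an estimated correlation, with fry and with permuted list scores. Leaving out each library gave 7 to 16 lists, 1 to 6 higher and 5 to 10 lower. Calls higher numbered 3 with the library set as a term, with the first set alone, with the second set alone and with 1 surrogate variable, and calls lower numbered 15 with the second set alone, where a lone mock library is assumed to vary like the EDN1 libraries. The cause was not tested. Of the 14 lists, 5 kept their call in all 8 leave-one-out runs. The epithelial-mesenchymal transition list, not called, turned from up to down without EDN1 4 (camera adjusted p = 0.709, with 0.302 to 0.963 over the leave-one-out runs), with the library set as a term (0.953), in the second set alone (0.967) and with 1 surrogate variable (0.988).

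Of 79 named genes, 3 changed sign, all among the most counted and none past the threshold. The FN1 log2 fold change (0.07) was -0.185 with the library set as a term, -0.249 in the first set alone, -0.0783 in the second, -0.159 with 1 surrogate variable and -0.189 in DESeq2 with the set (-0.321 to 0.302 over the leave-one-out runs). The RPS27A log2 fold change (0.04) was -0.0600 with the set as a term, -0.132 in the first set alone, -0.0458 and -0.0331 with 1 and 2 surrogate variables and -0.0636 in DESeq2 with the set (-0.0743 to 0.145). The HSP90AB1 log2 fold change (0.09) was -7.34e-04 with the set as a term, -0.00138 and -0.0111 in the first and second set alone, -0.022 with 2 surrogate variables and -0.00444 in DESeq2 with the set (-0.0138 to 0.193). The other named genes kept their sign but were mostly picked by p in the same libraries, so this is not independent evidence: over all genes, 24.8% had the other sign in the second set alone and 20.9% in the first. In 14 cases over 9 genes a named gene newly passed, some of them named because of it.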

Other observations

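The tests of the split of mock 4, EDN1 3 and EDN1 4, the tests of the cholesterol list and the counts over other splits were chosen after the results were seen. The split of 4 against 4 used for the tests of GC content and length was also picked after the results were seen, by its count of genes called.

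Several genes were called by some tools and not by edgeR's main test. TAGLN2, an actin-binding protein gene, averaged 50.7 ± 11.2 CPM in mock and 96.9 ± 18.8 CPM in EDN1 overexpression (SD, n = 4), a log2 fold change of 0.93 (SE 0.19). It passed in DESeq2 with the library set as a term (adjusted p = 1.75e-04) and in edgeR's quasi-likelihood test with 2 surrogate variables (adjusted p = 0.024, Benjamini-Hochberg), while its adjusted p ranged up to 1.00 over its 26 alternatives. AFP, the alpha-fetoprotein gene, averaged 1028 ± 375 CPM in mock and 595 ± 295 CPM in EDN1 overexpression (SD, n = 4), a log2 fold change of -0.79 (SE 0.35) that ran from -1.16 without EDN1 4 to -0.51 without mock 4. It was -1.05 within the first library set and -1.02 within the second, and passed only in DESeq2 with the library set as a term (adjusted p = 0.0287). DESeq2 with the set also called PRSS56 (adjusted p = 0.0461), and edgeR's quasi-likelihood test with 2 surrogate variables called S100A14 (adjusted p = 0.00469, Benjamini-Hochberg) and DNAJC12 (0.024). These genes were chosen after their values were seen.

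As many genes as in the real split (1) were called in 2 of the 35 splits of the 8 libraries into 4 and 4, so the count alone does not exclude chance. The gene called was EDN1, which was called in 1 of the 35 splits, the real one. The highest other count was 758, for mock 1, mock 3, EDN1 1 and EDN1 2 against the rest, and the other 33 splits gave 0. A split that calls so many genes points to a structure of the samples other than the group, and with the library set as a term the count was 1. As many lists as in the real split (14) were called in 6 of the 35 splits, with 15 as the highest other count, so chance could not be excluded for the lists either.

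The pattern behind that split was sharper between mock 4, EDN1 3 and EDN1 4 and the other 5 libraries, where 2132 genes were called without the group as a term. The calls of the split of 4 against 4 were 741 among genes with a GC value and 765 after each library's GC trend was removed. This argues against a trend on whole-transcript GC content as the whole cause. The calls were 758 over all genes and 715 after the length trend was removed. Since the kit reads tags near transcript ends, counts need not follow gene length, so the length result decides little. The GC content of the tags themselves was not tested. For the split of 3 against 5, the calls went from 2033 to 1984 after the GC trend was removed, which argues against whole-transcript GC content. They went from 2132 to 2014 after thinning to the smallest library total. Library totals overlapped between the sets, with 9132441 to 14932385 counts in the second and 8409173 to 12466094 in the first. Thinning thus had little difference in depth between the sets to remove, so its result does not decide on depth. The level of EDN1 was higher in EDN1 3 and EDN1 4 than in EDN1 1 and EDN1 2, but mock 4 shared the pattern: its difference from the other mock libraries correlated across genes at 0.822 with that of EDN1 3 and EDN1 4 from EDN1 1 and EDN1 2, where the highest of the other pairings was 0.515 (genes are not independent replicates). The set of mock 4, EDN1 3 and EDN1 4 was formed from these same counts, so the correlation describes the pattern and is no independent test. A library or culture batch not given in the labels may be the source, as a hypothesis that was not tested.

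The cholesterol synthesis score was 0.47 higher on average in EDN1 overexpression (exact permutation p = 0.0571), and camera's call of the list at the preset correlation was lost (adjusted p = 0.36 with an estimated correlation). With the library set as a term the score difference was 0.48 (SE 0.20, 95% interval -0.05 to 1.00), against 0.47 without it. The set's own effect on the score was -0.04 (95% interval -0.58 to 0.50). With set shares that differ by 0.25 between the groups, the upper end of that interval gives 0.12 of the 0.47. The whole 0.47 would need a set effect of 1.86, while scores ran only from -0.33 to 0.55. The near balance of the sets thus fixed this result in advance. It limits what the set can add to the pooled difference, but it is no test of the set as a cause. After the GC trend was removed the difference was 0.47, which argues against whole-transcript GC content. The GC content of the tags was not tested. An effect of EDN1 overexpression on sterol synthesis genes and a culture difference of EDN1 1 and EDN1 3 may each account for the pattern if it is not chance, and 4 libraries per group with 2 high and 2 near the mock range leave both open.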
